A study of Danio rerio with 6 samples.

How the data were processed

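Livers of adult male zebrafish (Danio rerio) were profiled by RNA sequencing after 3 weeks in water with the vehicle ethanol (control), with 1000 nM 17β-estradiol (E2, the main natural estrogen) or with 100 nM nonylphenol (NP, an alkylphenol breakdown product of surfactants that can bind estrogen receptors). Per the labels' protocols, each group was kept in 1 tank of 80 L holding 40 fish, RNA was extracted with TRIzol, purified on columns and treated with DNase, and libraries were made with a TruSeq RNA kit. Each of the 3 groups has 2 libraries. The labels do not say whether a library holds 1 fish or a pool, so p-values of genes measure only the spread between these libraries, which may be technical. Tank and treatment cannot be told apart, and the concentrations of the 2 compounds differ.

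The submitters' processing notes name TopHat2, HTSeq, DESeq2 and the genome build GRCz10, without versions or settings. Per the file headers, the authors deposited 2 tables of their own comparisons, E2 against control and NP against control, and the tables used here hold no values per library. Each table has 32760 rows for 31953 gene IDs; repeated rows of an ID hold identical values and were counted once. The deposited signal of each gene is its mean normalised read count over the 4 libraries of the comparison. The deposited log2 fold changes and their standard errors come from the authors' fit, as does the score of each gene, which equals the log2 fold change divided by its standard error (a Wald statistic). The deposited p-values are two-sided normal p-values of that score, and the deposited adjusted p-values are Benjamini-Hochberg values over the genes that have one. An adjusted p was given for 3241 of 17208 genes with reads in the E2 table, from a mean of 12.6 upward, and for 6799 of 18067 in the NP table, from a mean of 6.64 upward. The design fixed before the data were examined expected counts per library. It named the authors' deposited values as the main result for tables without values per library, and that rule was followed. The threshold was an adjusted p under 0.05, and "rose", "fell" and "called" refer to it.

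The genes named in the text were fixed by a rule before the data were examined: the vitellogenins and estrogen receptors; the 10 largest rises and 10 largest falls past the threshold with a mean of at least 2, an informative symbol and treated libraries that did not overlap the controls; and up to 4 members of each fixed gene list with the smallest adjusted p, or the 2 with the smallest p where none passed. The condition on overlap was applied where reads per library had been recovered, as described next. A total of 40 gene lists (pathways, markers of liver and other cell types, and sample quality) were fixed by symbol. Of 31953 gene IDs, 26121 were found in a table of current names, which was used beside the names in the files. Lists with 5 or more tested members were compared with all other tested genes by limma's cameraPR on the deposited scores, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. This replaced camera on expression values, which the design had named. The median log2 fold change over all tested genes was -0.22 for E2 and -0.03 for NP in the authors' deposited tables, and list medians are given without subtracting it. Deposited fold changes were drawn toward 0: in 60 of 60 called genes with over 3 recovered reads in both groups for E2, and 98 of 98 for NP, they were smaller in size than the ratio of the recovered means.

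As a check added after seeing the data, whole read counts were recovered from the deposited means. A mean of 4 normalised counts is a sum of whole reads, each worth a fixed step per library, and the lowest means of a table repeat these steps. The steps gave the size factor of each library, and each gene's mean in the 2 tables, with the direction of its fold change, was then solved for 6 whole counts. A unique solution was found for 18267 of 18593 genes with reads (98.2%). The other 326 genes, whose means were too high, were not solved, and among them are most vitellogenins. The recovered genes hold 36.3% of the summed means in the E2 table and 29.3% in the NP table. In 13897 genes solved in each table alone, the 2 control counts were the same in both tables for all 13897. Of 18267 altered means tried as decoys, 3 had a solution. On simulated tables, 2771 of 2771 solved genes had all 6 counts right. The steps cannot be tied to a sample of a group, so libraries are called the deeper and the shallower library of their group, by size factor.

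Size factors are given relative to the smallest, that of the shallower E2 library. That of the deeper E2 library was 5.92 times as large. Those of the control libraries were 14.3 and 9.09 times as large, and those of the NP libraries 8.07 and 7.83 times. Reads summed over the recovered genes, deeper library first, were 441440 and 264474 in the controls, 228289 and 17547 in E2, and 275982 and 295191 in NP. These sums differ in other proportions than the size factors. By the size factors, a read in the shallower E2 library weighs 14.3 times as much as one in the deeper control. After scaling, the median log2 ratio of the deeper to the shallower library was 0.957 in E2, 0.0800 in control and 0.0280 in NP. It was taken over genes with a mean of at least 50 normalised reads and reads in both libraries. Floors cover counting error only, and the bootstrap intervals cover the spread between genes.

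Recovered reads were tested with limma-voom in 1 fit of all 6 libraries, over 3592 genes with a mean normalised count of 10 or more. NP was contrasted with E2 in that fit only, at gene and at list level. For comparisons normalised in separate tables the design had left this contrast untested, so it is an addition. Lists were tested on the same reads with camera at the preset and at an estimated correlation, and with fry. On simulated reads for the 3592 genes with the dispersion of the control pair (0.472), limma-voom called 3.03% of genes changed 4-fold, 44.9% of those changed 16-fold and 64.6% of those changed 64-fold in E2 against control, and 6.25%, 54.7% and 86.9% in NP against control. Of the 78 and 101 calls in these simulations, 3.85% and 2.97% were false. All simulated genes shared this 1 dispersion, which may make the simulated shares of changed genes called too high in both comparisons. For E2 they may be too high also because its libraries differed more than the controls (median 3.93-fold against 1.94-fold). For a gene with no reads in either library of a group, a fold is given as a bound computed with 3 reads over the group. Log2 ratios of recovered reads used a pseudocount of 0.5 normalised reads.

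Both comparisons share the 2 controls, so the correlation of their fold changes and the overlap of their most extreme ratios were set beside 100 simulated experiments with unchanged groups. Alternatives covered the filter on low means, the threshold, the test, the correlation between genes, each library left out and unshared controls. Software was limma 3.58.1 in R 4.3.3, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No genome was used, so no coordinates are given. The text gives values for part of the genes that the rule for named genes takes, and the others are not reported here.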

Results

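Liver transcripts of adult male zebrafish were measured by RNA sequencing in 3 groups of 2 libraries: vehicle control, 17β-estradiol (E2) at 1000 nM and nonylphenol (NP) at 100 nM, each after 3 weeks of exposure. The values are the authors' own comparisons of E2 with control and of NP with control, over 17208 and 18067 genes with reads. Depth differed between the libraries as read from the deposited means. The shallower E2 library had 17547 reads over the recovered genes and the deeper E2 library 228289, against 441440 and 264474 in the controls and 275982 and 295191 in NP. Among genes with a mean of at least 50 normalised reads, the median fold between the 2 libraries of a group was 3.93 in E2 (610 genes), 1.94 in control (703 genes) and 1.36 in NP (775 genes).

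The comparison of E2 with control asked what a strong natural estrogen changed in the male liver. Vitellogenins, the egg yolk precursor proteins that the liver of females makes under estrogen, rose most. All 8 vitellogenin genes rose, with a median log2 fold change of 8.40 in the authors' deposited table, and 8 rose when adjusted over the list alone (list test adjusted p = 1.22e-37). In the authors' deposited table vtg6 rose by 9.87 ± 1.1 (authors' SE, log2; adjusted p = 6.46e-16), vtg7 by 9.47 ± 1.03 (adjusted p = 1.59e-16), vtg4 by 8.94 ± 1.07 (adjusted p = 9.12e-14) and vtg3 by 8.45 ± 1.15 (adjusted p = 1.33e-10). The authors' deposited table gave 8.35 ± 1.13 for vtg2, 6.74 ± 1.14 for vtg5 and 6.50 ± 1.09 for vtg1. The eighth gene, vtg8 (named si:dkey-4c23.3 in the files), had 19 recovered reads in E2 and 0 in control, at least 21.4-fold higher with a floor of 3 reads over the group. Reads shared between similar vitellogenin genes were not examined, so the division of reads among these genes is uncertain.

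Of the estrogen receptors, esr1 rose by 6.45 ± 1.3 (adjusted p = 1.13e-04) in the authors' deposited table, with 275 and 7 recovered reads in the deeper and shallower E2 libraries against 3 and 1 in the controls. The other receptors did not pass: the authors' deposited table gave esr2b at 0.26 ± 1.2 (adjusted p = 0.947) and esr2a at 0.68 ± 1.49, without an adjusted p. The list of estrogen receptors and estrogen-responsive genes had 2 members that rose, esr1 and nothepsin (nots), and 3 that did not pass, and 2 rose when adjusted over the list alone (median 1.35 in the authors' deposited table, list test adjusted p = 0.00174). Nothepsin, an aspartic protease, rose by 7.18 ± 1.19 (adjusted p = 6.06e-07) in the authors' deposited table. Too few members of this list and of the vitellogenins had recovered reads for an estimated correlation.

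Other large rises were rcn3 (7.92 ± 1.27), which encodes a calcium-binding protein of the secretory pathway, fam20cl (7.33 ± 1.35), a member of a family of secretory pathway kinases, and rtn1a (7.22 ± 1.19), a reticulon of the endoplasmic reticulum, in the authors' deposited table. fam46c had 70 recovered reads in E2 and 0 in control, at least 78.9-fold higher. Genes of the translocon and secretory pathway shifted upward as a list, with a median of 0.65 in the authors' deposited table. Of 44 members, 1 rose (mcfd2, a cargo receptor subunit, 3.62 ± 1.11), 43 did not pass, and 0 passed when adjusted over the list alone by the Benjamini-Hochberg method. The list test gave adjusted p = 0.00634, and adjusted p = 0.576 with an estimated correlation. Among 26 ER chaperone and unfolded protein response genes 1 rose (trib3, 3.81 ± 1.13 in the authors' deposited table), as 1 did adjusted over the list alone, and the list did not pass (adjusted p = 0.0592). The authors' deposited table also had rises of hmgcra (4.47 ± 1.3), the rate-limiting enzyme of cholesterol synthesis, sult2st3 (5.61 ± 1.31), a sulfotransferase, and gpam (6.19 ± 1.61), an enzyme of triglyceride synthesis. The 123 reads of gpam in E2 were all in the deeper library, and without that library its reads lay in the opposite direction. The lists of these genes did not shift upward past the test. Of 14 cholesterol synthesis genes 1 rose and 13 did not pass, with 1 rising when adjusted over the list alone (median -0.35 in the authors' deposited table, test direction upward, adjusted p = 0.711). Of 11 fatty acid and triglyceride synthesis genes 1 rose, 1 fell and 9 did not pass, with 2 rising and 2 falling when adjusted over the list alone (median -1.14 in the authors' deposited table, adjusted p = 0.392). Xenobiotic metabolism genes, which include sult2st3, shifted downward: 1 of 25 rose, 24 did not pass, and 1 rose and 3 fell when adjusted over the list alone. Their median was -1.57 in the authors' deposited table, with adjusted p = 0.0442, and adjusted p = 0.642 with an estimated correlation.

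**Figure D1:**
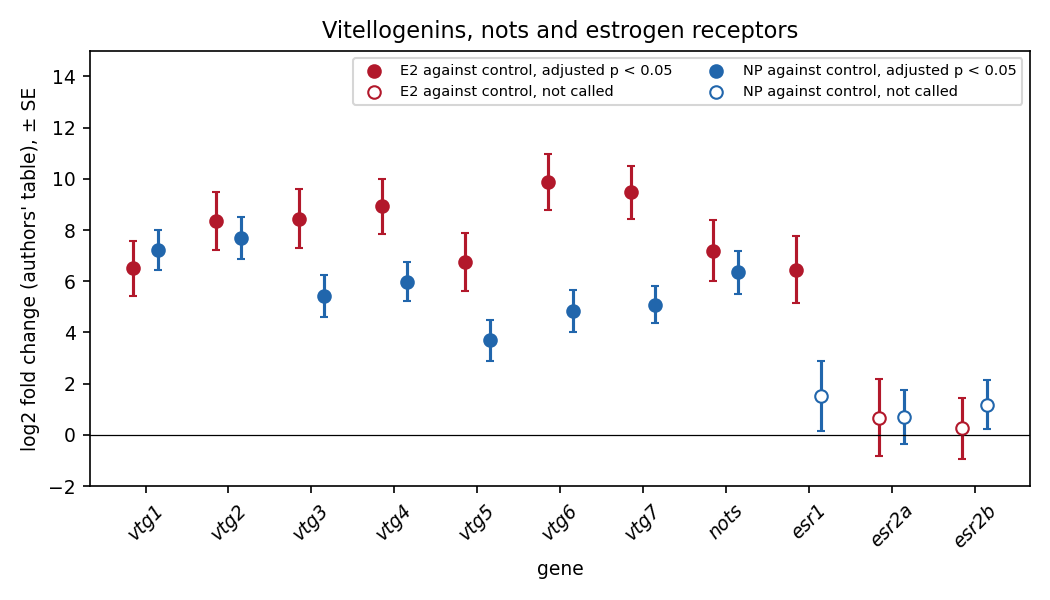
Log2 fold changes of vitellogenins, nots and estrogen receptors (y axis, authors' deposited table, bars ± the authors' SE) in E2 against control (red) and NP against control (blue); filled points passed an adjusted p of 0.05. The 7 vitellogenins and nots passed in both comparisons, and esr1 passed in E2 (6.45) and not in NP (1.52).

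Complement and acute phase genes, secreted by the liver in innate defence, shifted downward as a list in E2. Of 41 members 11 fell, 0 rose and 30 did not pass, and 20 fell when adjusted over the list alone (median -2.45 in the authors' deposited table). The list test gave adjusted p = 5.16e-14, and adjusted p = 0.35 with an estimated correlation. Haptoglobin (hp), which binds free haemoglobin, changed by -6.73 ± 1.17 (adjusted p = 1.98e-06), the chemotactic factor lect2l by -6.07 ± 1.27, and the complement components c3a.2 and c3a.3 by -5.83 ± 1.18 and -4.97 ± 1.11 in the authors' deposited table. Serum amyloid A (saa) had 0 reads in E2 and 469 in control, at least 46.2-fold lower, and 466 of the 469 were in the deeper control.

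Markers of macrophages and antigen-presenting cells fell in 4 of 11 members, with 7 not passing and 6 falling when adjusted over the list alone (median -3.59 in the authors' deposited table). This list had adjusted p = 1.23e-05, and adjusted p = 0.35 with an estimated correlation. The granulin genes grn1 and grn2 changed by -6.41 ± 1.4 and -4.39 ± 1.32 in the authors' deposited table. Type I interferon response genes fell in 2 of 8 members, mxc (-5.73 ± 1.57) and socs1a, with 6 not passing and 6 falling when adjusted over the list alone (median -3.58 in the authors' deposited table). socs1a had 0 reads in E2 and 212 in control, at least 20.9-fold lower, and 208 of the 212 were in the deeper control. mxc had 1 and 0 reads in E2, against 597 in the deeper and 15 in the shallower control. The test of the interferon list gave adjusted p = 4.7e-04, and adjusted p = 0.642 with an estimated correlation. On recovered reads of 7 of its members, camera at the preset correlation gave adjusted p = 0.0618. The controls differed in both groups of genes. Summed normalised reads of the interferon genes were 784 in the deeper and 205 in the shallower control, against 120 and 32.1 in E2, and those of the macrophage genes were 1194 and 638, against 184 and 123. On recovered reads, 26 macrophage genes with over 3 control reads had a median log2 ratio of E2 to control of -1.32 without the deeper control and -2.81 without the shallower, and 20 interferon genes had -1.25 and -3.08. Immediate early genes, which respond to stress and handling within minutes, shifted downward as a list: 1 of 16 fell (cebpd, -3.88 ± 1.28), 15 did not pass and 1 fell when adjusted over the list alone. Their median was -1.74 in the authors' deposited table, with adjusted p = 0.00718, and adjusted p = 0.35 with an estimated correlation.

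Of the lists of liver metabolism and secreted proteins some passed downward in E2 and others did not pass. Apolipoproteins and lipid transport genes fell in 6 of 23 members and 17 did not pass, with 10 falling when adjusted over the list alone (median -1.94 in the authors' deposited table; adjusted p = 1.77e-05, and adjusted p = 0.576 with an estimated correlation). Among them were apobb.2 (-4.93 ± 1.33), a structural protein of lipoproteins, and apoeb (-4.39 ± 1.02) in the authors' deposited table. On recovered reads of 14 members of this list, camera at the preset correlation gave adjusted p = 0.0618. Coagulation and fibrinolysis genes fell in 3 of 25 members, f5 (-4.34 ± 1.18) and the fibrinogen genes fga (-3.60 ± 1.01) and fgb (-3.58 ± 1.01), and 22 did not pass in the authors' deposited table. In this list 5 fell when adjusted over the list alone, and the list test gave adjusted p = 3.12e-05, and adjusted p = 0.35 with an estimated correlation. Glycolysis and gluconeogenesis genes fell in 3 of 25 members, among them glycogen phosphorylase pygl (-5.79 ± 1.45) and fbp1b (-4.74 ± 1.3), and 22 did not pass in the authors' deposited table. Here 5 fell when adjusted over the list alone, with adjusted p = 2.33e-04 for the list, and adjusted p = 0.35 with an estimated correlation. Amino acid and urea cycle genes fell in 3 of 32 members, among them bhmt (-3.94 ± 1.21 in the authors' deposited table), and 29 did not pass. Of these genes 4 fell when adjusted over the list alone, with adjusted p = 4.7e-04 for the list, and adjusted p = 0.61 with an estimated correlation. Hepatocyte markers, which share fga, fgb and other genes with these lists, fell in 4 of 26 members and 22 did not pass, with 7 falling when adjusted over the list alone. Their median was -1.91 in the authors' deposited table, with adjusted p = 1.96e-04, and adjusted p = 0.773 with an estimated correlation. On recovered reads of 7 members, camera at the preset correlation gave adjusted p = 0.477. Summed normalised reads of 8 recovered hepatocyte markers were 438 in the deeper and 497 in the shallower E2 library. These lay between the 279 of the deeper and the 961 of the shallower control. Of 8 steroid conversion genes 2 fell and 6 did not pass, with 3 falling and 1 rising when adjusted over the list alone, and the list did not pass (adjusted p = 0.235). Those that fell were hsd11b2 and hsd11b1la. The glucocorticoid-converting enzyme hsd11b2 had 0 reads in E2 and 351 in control, at least 34.6-fold lower. The other, hsd11b1la, had 0 and 137, at least 13.5-fold lower. Fatty acid oxidation (0 of 22 genes, adjusted p = 0.235), the citrate cycle (0 of 21, adjusted p = 0.696) and nuclear genes of oxidative phosphorylation (0 of 68, adjusted p = 0.228) did not pass, with 0 members passing when adjusted over the list alone. Neither did bile acid genes (0 of 10, adjusted p = 0.246), where 1 rose and 3 fell when adjusted over the list alone.

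Transcripts of other tissues also differed between the libraries. Exocrine pancreas markers rose in 2 of 14 members in E2, prss59.1 (4.21 ± 1.27) and cpb1 (4.84 ± 1.53), and 12 did not pass in the authors' deposited table. When adjusted over the list alone 10 rose, and the list test gave adjusted p = 9.55e-07, and adjusted p = 0.642 with an estimated correlation. Their summed normalised reads were 128 in the deeper and 1342 in the shallower E2 library, against 4.49 and 91.8 in the controls. These came from 142 and 251 reads in E2 and from 12 and 156 in the controls, where NP held 9464 and 28760. Whether reads were carried over from the NP libraries into E2 was not tested. Intestine markers had 5 members tested, of which 0 passed by the authors' test, 4 fell when adjusted over the list alone, and the list test gave adjusted p = 0.0122 (median -4.02 in the authors' deposited table). Of their normalised control reads, 28.4 were in the deeper and 580 in the shallower control.

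In all, 187 of 3241 genes passed in E2 against control, of which 68 rose and 119 fell, and 628 had an unadjusted p under 0.05. Of the 40 lists 29 were tested and 18 passed, 4 upward and 14 downward, of which 14 had enough recovered members for an estimated correlation. Of the 29 lists tested on recovered reads 0 passed camera with an estimated correlation (2 at an unadjusted p under 0.05), with fry, which tests against no change and not against other genes, passing glycolysis and bile duct markers. Bile duct markers had 3 members tested here, too few for the main list test. Of 139 called genes with recovered reads, 123 had E2 libraries that did not overlap the controls. Chance gives 16.7% in a given direction for genes not chosen for a difference, which these were, so the share is no test of them. Without the deeper E2 library 8 of the 57 risen genes lay in the opposite direction. limma-voom on the recovered reads called 0 of 3592 genes, with 553 at an unadjusted p under 0.05. Without the deeper E2 library 3 lists passed camera on the recovered reads, and without the shallower control 11, against 15 with all libraries.

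The comparison of NP with control asked whether a weak environmental estrogen changed the same tissue. Digestive enzymes of the exocrine pancreas rose most. Of 25 markers 22 rose and 3 did not pass, and 24 rose when adjusted over the list alone (median 6.57 in the authors' deposited table). The list test gave adjusted p = 8.41e-125, and adjusted p = 0.324 with an estimated correlation. Trypsin-like prss59.1 rose by 8.16 ± 0.80 (adjusted p = 1.12e-20), the elastase genes CELA1 (1 of 7) by 8.12 ± 0.86 and ela2 by 7.90 ± 0.81, and the carboxypeptidase cpb1 by 7.54 ± 0.90 in the authors' deposited table. Chymotrypsin genes ctrb1 (7.48 ± 0.91) and ctrl (7.44 ± 0.88), cpa5 (7.45 ± 0.90) and prss59.2 (7.55 ± 0.87) rose by similar amounts in the authors' deposited table. Summed normalised reads of the list were 6272 in the deeper and 19632 in the shallower NP library.

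Vitellogenins rose in NP as well. All 7 tested genes rose, as 7 did adjusted over the list alone (median 5.42 in the authors' deposited table, list test adjusted p = 3.93e-46). In the authors' deposited table vtg2 rose by 7.69 ± 0.81 (adjusted p = 3.49e-18), vtg1 by 7.23 ± 0.77 (adjusted p = 9.73e-18), vtg4 by 5.98 ± 0.77 and vtg3 by 5.42 ± 0.82. The authors' deposited table gave 5.09 ± 0.71 for vtg7, 4.84 ± 0.83 for vtg6 and 3.69 ± 0.80 for vtg5 (adjusted p = 3.74e-04). Nothepsin rose by 6.35 ± 0.85 (adjusted p = 2.41e-11) in the authors' deposited table. It was the member that rose of 7 in the estrogen list, where 6 did not pass and 1 rose when adjusted over the list alone (list test adjusted p = 0.00545). The receptor esr1 had 13 and 0 recovered reads in the NP libraries and 1.52 ± 1.36 in the authors' deposited table, without an adjusted p. The values of esr2b and esr2a were 1.19 ± 0.96 (adjusted p = 0.963) and 0.70 ± 1.04 (adjusted p = 0.999) in the authors' deposited table. For vtg8 0 reads were found in NP and in control.

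Markers of macrophages and genes of the interferon response shifted downward in NP. Macrophage and antigen-presenting cell markers fell in 6 of 16 members and 10 did not pass, with 9 falling when adjusted over the list alone (median -2.13 in the authors' deposited table; adjusted p = 1.14e-12, and adjusted p = 0.324 with an estimated correlation). grn1 changed by -3.30 ± 0.70 in the authors' deposited table, and mhc2dab, an antigen-presenting MHC class II gene, had 0 reads in NP and 124 in control, at least 28.1-fold lower. Type I interferon response genes fell in 3 of 13 members and 10 did not pass, with 7 falling when adjusted over the list alone (median -2.33 in the authors' deposited table; adjusted p = 4.56e-10, and adjusted p = 0.324 with an estimated correlation). Among them mxc changed by -4.76 ± 1.02 in the authors' deposited table, and stat1b had 0 reads in NP and 162 in control, at least 36.7-fold lower, with 157 of the 162 in the deeper control. On recovered reads the median log2 ratio of NP to control was -1.36 without the deeper control and -2.49 without the shallower for 26 macrophage genes, and -1.04 and -2.62 for 20 interferon genes. Immediate early genes fell in 5 of 18 members and 13 did not pass, with 7 falling when adjusted over the list alone. Their median was -1.19 in the authors' deposited table, with adjusted p = 3.71e-08, and adjusted p = 0.324 with an estimated correlation. Examples were junba (-3.53 ± 0.91), fosl2 (-3.44 ± 0.97) and egr1 (-3.12 ± 0.92) in the authors' deposited table. Among the largest falls were also the chemokine ccl19a.1 (-6.23 ± 1.08), with 1499 reads in the deeper and 9 in the shallower control, and hepcidin (hamp, -6.08 ± 0.99), with 974 and 46, in the authors' deposited table. The neutrophil peroxidase mpx had 0 reads in NP and 89 in control, at least 20.2-fold lower, with 43 and 46 in the controls. Its list, neutrophil markers, did not pass (adjusted p = 0.872): of 6 members 1 rose (cpa5, also a pancreas marker), 1 fell (mpx) and 4 did not pass, and 1 rose and 2 fell when adjusted over the list alone.

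Complement and acute phase genes fell in 5 of 47 members and 42 did not pass, with 9 falling and 1 rising when adjusted over the list alone (median -0.54 in the authors' deposited table, adjusted p = 9.39e-05). On recovered reads of 19 members the direction was upward, with adjusted p = 0.761 at the preset correlation and adjusted p = 0.857 with an estimated correlation. The members that fell included hp (-7.11 ± 0.85, adjusted p = 2.35e-14) and C7 (2 of 2), a complement component (-6.35 ± 0.94, adjusted p = 2.98e-09), in the authors' deposited table. Intestine markers fell in 2 of 9 members, cldn15la (-4.49 ± 1.07) and mep1a.1 (-4.35 ± 1.21), and 7 did not pass in the authors' deposited table. In that list 3 fell when adjusted over the list alone, and the list test gave adjusted p = 0.0011. Its median was -1.84 in the authors' deposited table and -2.48 with genes at 0 in a group set to their bound. The intestinal genes muc13b and MGAM2, with 0 reads in NP, had 194 of 214 and 106 of 112 control reads in the shallower control.

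Lists of ER chaperones and of cholesterol synthesis shifted downward in NP. ER chaperone and unfolded protein response genes had a median of -1.07 in the authors' deposited table: 1 of 30 fell (hspa5, the chaperone BiP, -3.22 ± 0.85), 29 did not pass and 6 fell when adjusted over the list alone. The list test gave adjusted p = 7.32e-07, and adjusted p = 0.324 with an estimated correlation. Cholesterol synthesis genes had a median of -1.19 in the authors' deposited table, where 1 of 21 fell (hmgcs1, -3.68 ± 0.85), 20 did not pass and 6 fell when adjusted over the list alone. This list had adjusted p = 2.4e-04, and adjusted p = 0.324 with an estimated correlation. Xenobiotic metabolism genes rose in 4 of 50 members, fell in 1 and did not pass in 45, and the counts were the same adjusted over the list alone (median 0.80 in the authors' deposited table; adjusted p = 1.81e-04, and adjusted p = 0.324 with an estimated correlation). Of these the cytochrome cyp1c1 had 62 reads in NP, 55 in the deeper and 7 in the shallower library, and 0 in control, at least 30.4-fold higher, and the glutathione transferase gstm.1 rose by 3.03 ± 0.77 in the authors' deposited table. Among glycolysis and gluconeogenesis genes 1 of 29 rose (pck1, 3.02 ± 0.71 in the authors' deposited table), as 1 did adjusted over the list alone, and 28 did not pass. The list gave adjusted p = 0.0388, and adjusted p = 0.324 with an estimated correlation. Hepatocyte markers shifted upward with 0 of 27 passing by the authors' test or adjusted over the list alone (median 1.04 in the authors' deposited table). The list test gave adjusted p = 6.83e-04, and adjusted p = 0.351 with an estimated correlation. Summed normalised reads of 8 recovered hepatocyte markers were 279 in the deeper and 961 in the shallower control, against 1162 and 1292 in NP. How much of this shift rests on the low deeper control was not tested.

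Transcripts of red blood cell markers were also higher in NP. Erythrocyte markers rose in 3 of 8 members, hbaa1 (2.98 ± 0.76), alas2 (2.79 ± 0.76) and cahz (2.94 ± 0.83), and 5 did not pass in the authors' deposited table. When adjusted over the list alone 4 rose, with adjusted p = 2.74e-06 for the list, and adjusted p = 0.324 with an estimated correlation. Their summed normalised reads were 225 and 575 in NP against 71.4 and 62.4 in control.

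**Figure D2:**
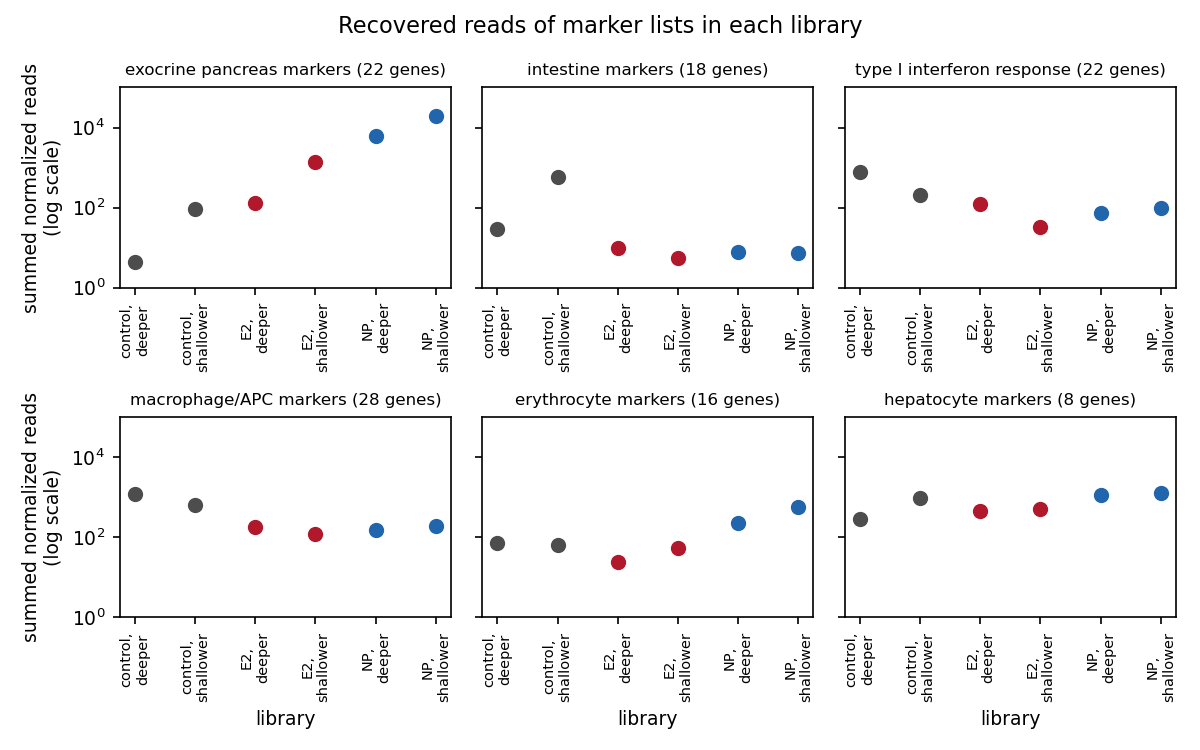
Summed normalised recovered reads (y axis, log scale) of 6 marker lists in each of the 6 libraries (x axis), 1 point per library, with no error bars because a point is a single library. Exocrine pancreas reads were 6272 and 19632 in NP and at most 1342 in the other libraries, and intestine reads were 580 in the shallower control and at most 28.4 elsewhere.

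In all, 200 of 6799 genes passed in NP against control, of which 86 rose and 114 fell, and 614 had an unadjusted p under 0.05. Of 34 lists tested 25 passed, 16 upward and 9 downward, of which 22 had enough recovered members for an estimated correlation. Of the 29 lists tested on recovered reads 0 passed camera with an estimated correlation (2 at an unadjusted p under 0.05), with fry passing bile duct markers alone, which were not among the 25 (adjusted p = 0.178). Of 176 called genes with recovered reads, 170 had NP libraries that did not overlap the controls, where the 16.7% of chance again holds only for genes not chosen for a difference. Genes that fell in NP had a median of 80.9% of their control level in the deeper control, against 50.6% over all tested genes. limma-voom on the recovered reads called 0 of 3592 genes, with 372 at an unadjusted p under 0.05. Without the deeper control 14 lists passed camera on the recovered reads, against 21 with all libraries.

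E2 and NP were then set side by side, to ask how far the responses to these exposures overlapped at concentrations that differ 1000 nM to 100 nM. Among 3146 genes tested in both, 14 rose in both, where 35 rose in E2 and 38 in NP and independent lists would share 0.423. They were vtg1 to vtg7, nots, fam20cl, the pancreatic genes prss59.1, cpb1 and CELA1 (1 of 7), and 2 genes with placeholder names. A total of 33 genes fell in both, where 119 fell in E2 and 88 in NP and independent lists would share 3.33. Among them were hp, lect2l, grn1, grn2, mxc, socs1a, lygl1, abca1b, muc13b and gpx1b. Both comparisons use the same 2 controls, so independent lists are not the value for no effect. Of 2820 genes with recovered reads, the 24 highest ratios in E2 and 27 in NP, as many as the calls, shared 13 genes, against 7.09 on average (1 to 12) in 100 simulations of unchanged groups with shared controls. The 82 and 75 lowest ratios shared 38, against 6.24 (0 to 12). The dispersion of the controls was taken as 1 value per range of means (0.259 to 0.588). Genes with a far wider gap between the controls, such as saa with 466 and 3 reads, may be too rare in the simulations. The simulated overlap may therefore be too low. Genes called as falling in both had a median of 81.0% of their control level in the deeper control, so part of the overlap may come from the shared controls. tgfbi, an extracellular matrix gene, fell in E2 (-5.52, adjusted p = 0.00728) and rose in NP (2.19, adjusted p = 0.0475) in the authors' deposited tables; it was singled out after its values were seen.

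The vitellogenin genes differed in their proportions. Over the 4 libraries of each comparison vtg1 and vtg2 held 28.0% and 29.3% of the summed means of vtg1 to vtg7 in the NP table, and 2.26% and 6.70% in the E2 table, in the authors' deposited tables. vtg7 and vtg6 held 30.9% and 19.4% in the E2 table, and 8.40% and 3.29% in the NP table, of the authors' deposited tables. These 7 genes made up 3.08% of all summed means in the E2 table and 0.307% in the NP table. The shares are pooled over libraries that may weigh unequally: vtg5, the gene of the 7 with recovered reads, had 400 and 2390 normalised reads in the deeper and shallower E2 libraries, and 217 and 52.6 in the deeper and shallower NP libraries.

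**Figure D3:**
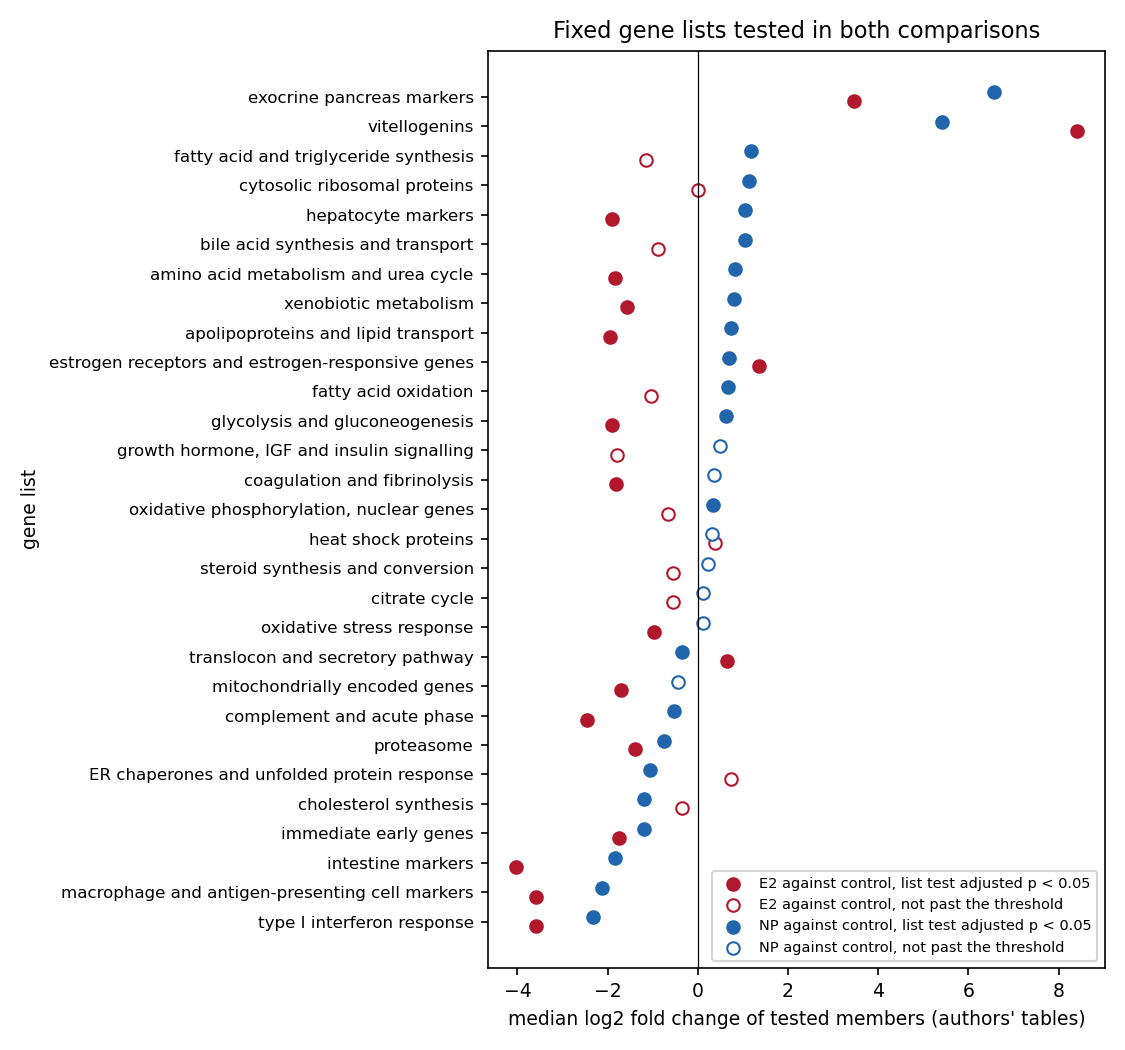
Median log2 fold change (x axis, authors' deposited tables) of the 29 gene lists tested in both comparisons, 1 red point for E2 against control and 1 blue point for NP against control per list; filled points passed the list test at the preset correlation. Pancreas markers (3.45 and 6.57) and vitellogenins (8.40 and 5.42) were highest, and hepatocyte markers lay at -1.91 in E2 and 1.04 in NP. On recovered reads, hepatocyte markers did not pass camera at the preset correlation in E2 (adjusted p = 0.477).

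The direct contrast of NP with E2 on recovered reads called 0 of 3592 genes by limma-voom, with 758 at an unadjusted p under 0.05. Among the genes with low p-values, none of which passed (each adjusted p = 0.112), were higher values in NP for ela2 (8.47 ± 1.27, log2 ± SE), ela2l (6.94 ± 1.24) and slc22a2 (4.68 ± 0.72), and lower values for rcn3 (-5.32 ± 0.77), mat2aa (-5.55 ± 0.87) and fkbp11 (-5.45 ± 1.0). The 4 lists lower in NP than in E2 at the preset correlation were ER chaperones (adjusted p = 5.01e-06), the translocon and secretory pathway (adjusted p = 9.77e-06), cholesterol synthesis (adjusted p = 0.0198) and heat shock proteins (adjusted p = 0.0304), each with adjusted p = 0.43 with an estimated correlation. Among the lists higher in NP were exocrine pancreas markers (adjusted p = 5.17e-13), amino acid metabolism (adjusted p = 9.8e-06) and coagulation (adjusted p = 4.32e-05), each with adjusted p = 0.43 with an estimated correlation. In all 16 of 29 lists passed at the preset correlation and 0 with an estimated correlation.

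Across the 3146 genes the log2 fold changes of the authors' deposited tables correlated with r = 0.342 and a covariance of 0.855; genes are not independent replicates. On recovered reads of 2820 genes r was 0.362 and the covariance 1.09, against a mean of 0.446 (0.390 to 0.478) and 0.396 (0.338 to 0.444) in 100 simulations of unchanged groups with shared controls. The observed r thus lay below the lowest simulated r, while the covariance exceeded its simulated mean by 0.697. The simulations took their spread from the controls, and the E2 libraries differed more (median 3.93-fold against 1.94-fold). A wider spread in E2 lowers r, so the comparison of r cannot decide on a shared response. With the deeper control used for E2 and the shallower for NP r was 0.273 and the covariance 0.712, and with the reverse they were -0.0700 and -0.281, so across these genes a shared direction was not shown apart from the shared controls. For a given number of reads the fold changes of the authors' deposited tables were close in some genes and apart in others. Of genes with 0 reads in E2 and in NP, chosen after their values were seen, stat1b had -5.25 and -5.54, eps8l3b -5.93 and -6.27, and saa -6.09 and -2.56 in the E2 and NP tables of the authors' deposited tables.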

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

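The filter on low means and the threshold were planned as alternatives before the data were examined. Fits with 4 libraries, an estimated correlation, fry, each library left out and unshared controls were also planned as kinds of alternative. These were run on the recovered reads, a step that was added after the data were seen. The other tests on recovered reads, the preset correlation of 0.05 and the ranks were chosen after the data were seen. The 187 genes in E2 became 72 without a filter on low means, 75 at an adjusted p under 0.01, 123 counting calls with recovered reads whose libraries do not overlap and 122 counting those still 2-fold with any 1 library left out; 170 had a mean of 20 or more. Only 139 calls had recovered reads, which lowers the last counts by construction. The 200 genes in NP became 127 at an adjusted p under 0.01 and 152 without a filter, and 164 of 176 stayed 2-fold with any 1 library left out. limma-voom called 0 genes in each comparison with all 6 libraries, with 4, at means of 3, 10 or 20 and with any library left out, against 553, 372 and 758 at an unadjusted p under 0.05 for E2, NP and NP against E2. All 136 authors' calls tested for E2 and all 127 for NP had the same direction in limma-voom. The reads were recovered from the authors' own means, so a like direction is no separate support for the calls. The cause of the lost calls was not tested. With any 1 library left out, as with all, limma-voom called 0, and of the calls with recovered reads 127 to 139 of 139 in E2 and 170 to 176 of 176 in NP were still 2-fold. The 18 lists in E2 became 11 at a mean of 20 or more. With camera at an estimated correlation 0 passed, where 14 of the 18 lists in E2 and 22 of the 25 in NP were tested. Camera on recovered reads at the preset correlation passed 15 lists in E2 with all libraries, and from 3 without the deeper E2 library to 20 with 1 left out. In NP it passed 21 with all libraries and from 14 without the deeper control to 20 with 1 left out. fry passed 2 lists in E2, glycolysis of the 18 and bile duct markers, too small for the main test, and 1 in NP, bile duct markers, not among the 25. Complement and acute phase genes in NP turned upward on recovered reads, with adjusted p = 0.761 by camera, 0.857 with an estimated correlation and 0.535 by fry, over 19 of 47 members. The correlation of 0.342 was 0.068 without called genes. On recovered reads, where it was 0.362, it became 0.273 and -0.0700 with unshared controls, and 0.272 to 0.482 over libraries left out. Of 121 named gene calls 86 held without a filter and 111 of 111 at a mean of 20 or more, and 0 turned direction in limma-voom with all libraries or with any 1 left out; by ratios of recovered reads 1 of 37 in E2, gpam, did so without the deeper E2 library, and 0 of 45 in NP without any library of the comparison. Of 43 list calls 32 held at a preset correlation of 0.05, 41 on ranks and 30 of 36 by camera on recovered reads. DESeq2 and edgeR, other size factors, library totals, normalisation without vitellogenins and pseudocounts or value filters were not run; the recovered reads, 36.3% and 29.3% of the summed means, leave out the most abundant genes. No paired analysis was possible because the labels pair no libraries. With 17547 reads in the shallower E2 library, genes of low level were not detectable there.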

Other observations

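The tests of explanations in this part were chosen after the results were seen; the gene lists were fixed before. Several lists moved in NP without any member that passed alone. Cytosolic ribosomal protein genes were higher as a list, with 0 of 81 passing by the authors' test or adjusted over the list alone (median 1.13 in the authors' deposited table; list test adjusted p = 1.35e-16, and adjusted p = 0.324 with an estimated correlation). Proteasome genes were lower, with 0 of 47 passing by either adjustment (median -0.76 in the authors' deposited table; adjusted p = 1.04e-05, and adjusted p = 0.324 with an estimated correlation). Fatty acid and triglyceride synthesis genes (0 of 19, median 1.18) and bile acid genes (0 of 12, median 1.04) were higher in the authors' deposited table, with adjusted p = 0.00548 and 0.00549, and adjusted p = 0.324 for each with an estimated correlation. Summed normalised reads of the first list were 226 in the deeper and 911 in the shallower control, against 2066 and 1246 in NP. Those of bile acid genes were 241 and 619, against 930 and 1203. How much of these shifts rests on the low deeper control was not tested. Stellate cell and fibroblast markers rose in 2 of 11 members, the collagen gene col1a1b (4.59 ± 0.94) and postnb (3.70 ± 1.02), fell in 1 and did not pass in 8 in the authors' deposited table. When adjusted over the list alone 4 rose and 1 fell, with adjusted p = 0.00163 for the list, and adjusted p = 0.324 with an estimated correlation. Circadian clock genes gave 0 of 19 and a median of 0.51 in the authors' deposited table, with adjusted p = 0.0388, and adjusted p = 0.366 with an estimated correlation.

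In E2, proteasome genes were lower as a list with 0 of 37 passing by either adjustment (median -1.40 in the authors' deposited table; adjusted p = 0.00942, and adjusted p = 0.576 with an estimated correlation). Mitochondrially encoded genes gave 0 of 13 and a median of -1.71 in the authors' deposited table, with adjusted p = 0.0325. Oxidative stress genes fell in 2 of 25 members, the ferritin gene fth1a (-3.38 ± 1.04) and gpx1b, and 23 did not pass in the authors' deposited table. When adjusted over the list alone 3 fell, with adjusted p = 0.0363 for the list, and adjusted p = 0.576 with an estimated correlation. Gonad and germ cell markers were too low to test: their recovered reads numbered 121 in the shallower NP library and at most 18 in the other libraries, and the 13 reads of piwil1 and the 15 of gsdf, a gonadal growth factor gene, were all in that NP library.

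Digestive enzyme genes were high in both NP libraries, led by prss59.1 and ctrb1, with means of 5061 and 2775 normalised reads in the authors' deposited table. Carry-over of reads from other libraries of the series was argued against, since the highest other library held 2.36% of the reads of the lower NP library over 19 recovered genes that rose. The log2 ratio of the 19 genes between the NP libraries ran from 0.459 to 2.26, with an interquartile range of 0.839 around a median of 1.72, against a range of 1.85 in 56 other risen genes, and 0.15% of 10000 random sets of those were as narrow. Pancreatic tissue dissected with the livers could give such a pattern, while an induction of these genes in liver cells by NP, which was not tested apart, stays open with 1 tank per group. Of the list, cpa5 is also in the neutrophil list, and endocrine pancreas markers had 3 and 17 reads in the NP libraries.

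Many of the genes that fell had 1 control library far above the other, so a fall could come from that library alone. The 25 genes that fell in both comparisons had a median log2 ratio of -3.99 without the deeper control, but they had been called against these controls; for genes with the lowest ratios of E2 to the deeper control, the median of NP to the shallower control was -1.27 (95% bootstrap interval -1.67 to -0.718), and with E2 and NP exchanged -1.60 (-2.18 to -0.581). Chosen with the shallower control and tested with the deeper, the medians were 1.1 (0.525 to 1.63) in NP and -2.41 (-3.32 to -1.39) in E2, which leaves open how much of these falls belongs to 1 control. For 17 intestine markers the median was 0 without the shallower control (-1.03 to 0) and -4.55 without the deeper, and intestinal tissue in that control or a fall in both treated groups cannot be told apart because 12 of the 17 had 3 or fewer reads in the other control; 5, among them cldn15la with 30 reads there, were still at least 2-fold lower in E2. For 48 interferon and immediate early genes in NP the median was -1.16 without the deeper control (-1.60 to -0.57) and -1.98 without the shallower. The 20 interferon genes had -1.04 and -2.62, which leaves open how much of their fall belongs to the deeper control. The 28 immediate early genes had -1.37 and -1.52, and summed normalised reads of their list were 787 in the deeper and 845 in the shallower control. Their median fall was thus of like size with either control left out, though single genes such as fosl2 (71.8 and 11.8) were higher in the deeper control. No interval was computed for these 28 genes, and the test had been set for the 48 together. The interval of the 48 without the deeper control reached above -1, so that test cannot decide whether the fall belongs to that control. An effect of the exposures on immune cells stays possible and was not tested apart from tank.

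Vitellogenin transcripts in the NP libraries might be reads carried over from the E2 libraries, in which case each gene would hold a like share of their sum in both tables. The share of vtg1 was 12.4 times as high in the NP table as in the E2 table, though shares per library are not known. Carry-over would bring a like percentage of each gene's E2 reads, and by the deposited means and size factors the NP reads of the 7 genes were at least 3.04% (vtg6) to 228% (vtg1) of their E2 reads. Of 40 other genes that rose in E2 and not in NP, 15 were under 3.04%. Among them were sult2st3 with 2 NP reads to 435 in E2 and si:ch211-170n20.3 with 0 to 165. The median of the 40 was 4.52%, so most lay above vtg6, and vtg7 (4.90%) lay near that median. With the shallower E2 library as the only source, 3 of 9 such genes lay under the lowest vitellogenin. The genes under it argue against carry-over as the whole source for the 7, less firmly for vtg6 and vtg7. Reads shared between near-identical copies were not tested, and neither was whether the proportions depend on the dose or on the compound.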
